A study of Bacillus subtilis with 7 samples.

How the data were processed

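A set of 7 one-colour (Cy3) Agilent tiling arrays was analysed, 1 for each of 7 time points of a submerged biofilm of *Bacillus subtilis* NDmed. Per the labels, 200 µL of culture at an OD of 0.02 were added to each well of 96-well plates, and 10 µg of total RNA were labelled per sample by reverse transcription with random primers, actinomycin D, which limits copying of the cDNA into a second strand, and added spike-in RNA. The labels give 1 sample per time point, so groups hold no replicates.

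The deposited scanner files hold the intensity of each spot. Per the file headers, the authors extracted them with Agilent Feature Extraction 10.7.3.1, which subtracts background and removes spatial trends within an array, and no step between arrays is recorded there. The deposited flags mark spots well above background, saturated or outlying. The deposited value table holds log2 values of 5737 rows. Per the labels limma was used, with its version and steps not given in the sources used here. The 7 columns share 1 distribution with a median of 9.97 each. Its scale is log2, its rows are not centred, and the names of its rows stay unknown, because they are numbered and no probe column matches them. It was used for counts only, and the part of the rule for named genes that asked for the same direction there could not be applied. The genome build is not given in the sources used here, and positions are those in the probe names, on the chromosome of the reference strain.

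Each array held 383238 non-control probes, of which 180777 carried a gene name and 202461 did not. Between 55.7% and 96.3% of them were well above background on each array, so the 75th percentile was taken over all probes. The main value was the log2 processed signal minus the 75th percentile of its array. Outlier spots (133 to 1078 per array) were left out, no probe was saturated, and 31 probes shared by several genes were left out. A feature's value was the median over its probes on its own strand (median of 23 probes), which gave 5942 features, 5940 with values on all arrays. These were 4241 locus tags, 1525 unnamed transcribed segments and RNA genes. Of the locus tags, 4237 were matched to symbols through the old locus tags of a reference gene table (ASM904v1), and the other symbols are those of the files. Because the median gene moved by more than 0.1 between arrays, levels of genes and lists, and their differences in the comparisons, are given relative to the median gene of each array. Scalings that move all genes of an array alike leave these values as they are.

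Before the data were examined, 3 comparisons were fixed: 7 h against 1 h, 24 h against 7 h and 48 h against 24 h. They have no test. Features counted if at least 50% of their probes were well above background on 1 of the 2 arrays, and those at least 4-fold apart were counted. Slide and scan day came from the files. Slide 1 held the 1 h and 7 h arrays, slide 2 the 3 h and 4 h arrays, slide 3 the 5 h array and slide 4 the 24 h and 48 h arrays. The 1, 3, 4 and 7 h arrays were scanned on day 1 and the others on day 2. Where no probe of a gene was well above background on 1 array, the fold is a lower bound against the lowest signal well above background there. After the data were seen this was extended to genes with fewer than 50% of their probes well above background on the array with the lower level, with the gene's own level there used where it was higher, and to list medians. The list calls were left as they were.

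The trend was fitted with limma 3.58.1 in R 4.3.3 (lmFit on log2 of the hours, eBayes with an intensity trend), with Benjamini-Hochberg adjustment over 5940 features and a threshold of 0.05. The scatter around the line stands for the error, so courses with a peak count as scatter. Gene lists were tested with camera (preset correlation 0.01, and estimated) and with fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. In the comparisons, the median of a list was set against 10000 random lists of the same size, matched in 20 bins of mean level. A list was called when it lay outside the middle 95% and at least 2-fold from 0. For heat shock at 24 h against 7 h the median was negative (-0.20) while the list lay above the random lists, which were lower still.

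The 45 lists, fixed beforehand from general knowledge of the species, were the *eps* operon, amyloid fibre and hydrophobin, matrix regulators, poly-gamma-glutamate, *ydaJKLMN*, flagellar basal body and chemotaxis operon, SigD late motility, competence, sporulation initiation, SigF and SigE, SigG and SigK sporulation genes, ribosomal proteins, aminoacyl-tRNA synthetases, RNA polymerase and translation factors, cell division, purine, pyrimidine, arginine, branched-chain, histidine and tryptophan synthesis, ATP synthase, nitrate respiration, fermentation, TCA cycle, glycolysis, gluconeogenesis, glycerol, acetoin, inositol and arginine use, SigB, heat shock, proteases, cannibalism toxins, surfactin, bacilysin, bacillaene, plipastatin, subtilosin, iron uptake, phosphate starvation, and the PBSX and SPβ prophages. In these, *sdpC*, *efeO* and *rocF* were not matched. Genes named in the text come from the 12 largest differences in each direction per comparison, among genes with a symbol, at least 3 probes and at least 80% of probes in the direction of the gene, up to 4 genes per called list, the 8 trend genes of smallest p per direction, and 17 genes fixed beforehand.

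Results were also computed with normexp background correction (offset 50), quantile normalization, scaling by the median gene, by 5 bright spike-in probes or by the percentile over probes detected on all arrays (40.3% of probes), the mean over probes, other fold thresholds, no filter, slide or scan day as a term, other time scales, each array left out, and the deposited log2 values. Chosen after seeing the data were quantile normalization of gene values, subtraction of the median signal of probes without a gene, 3 h in place of 1 h, 48 h in place of 24 h, and the sum of both strands, with the opposite strand taken as the median over at least 3 probes opposite to a gene. The sum was added because the 1 h array hardly separated the strands. It covers fewer features (4312 to 4845 compared).

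The scripts were tested on simulated data. For the trend over 5940 features, 71% of 100 genes with a slope of 1 and 4% of 100 with a slope of 0.5 were recovered, with 3 false calls. The noise there was drawn for each gene and array alone, with the size of the gene's scatter around the trend line. It holds no effect of slide or scan day shared by genes, so the 3 false calls do not carry over to the real trend. For pairwise differences over 4231 genes, simulated differences of 3 came back at a median of 3.00, with 0 false calls at 4-fold. Of simulated differences of 2, 40% passed 4-fold. The noise of the pairwise simulation was that between the 3 h and 4 h arrays, which share slide and scan day, drawn for each probe alone. It holds no differences between slides, scan days or strands, so the 0 false calls do not carry over to the comparisons. Of 200 lists drawn at random, 5.5% fell outside the 95% range. Both these lists and those they were ranked among were drawn gene by gene, so such a share followed from the design. The real lists hold genes that may move together, with estimated correlations from -0.0898 (glycerol use) to 0.998 (surfactin). How often a list of correlated genes falls outside the range by chance was not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.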

Results

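The data are 7 one-colour tiling arrays of *Bacillus subtilis* NDmed, an undomesticated strain, grown as a submerged biofilm on the bottom of microplate wells in TSB, a rich broth. Cells adhered at 30 °C for 90 min, the wells were rinsed and refilled, and total RNA was taken at 1, 3, 4, 5, 7, 24 and 48 h after adhesion. Each time point is 1 array, so no difference between 2 arrays has a replicate check, and the number of arrays limits the precision. The SE given with a gene's difference between 2 arrays is taken over its overlapping probes and covers measurement error within these arrays only. Levels and differences of genes are on the log2 scale, relative to the median gene of the same array. Where fewer than 50% of a gene's probes were well above background on the array with the lower level, its fold is given as a lower bound. This bound allows for background on that array only, and not for the signal carried by probes without a gene.

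The arrays differed in signal. The median signal of gene probes was 120 on the 1 h array and between 1122 and 2792 on the other 6. Probes of ribosomal RNA held 81.7% of the gene-probe signal at 1 h, 22.5% to 27.3% from 3 h to 7 h, 41.7% at 24 h and 42.1% at 48 h. The arrays also differed in how far they told the strands apart. Over 4198 genes, the signal on a gene's own strand exceeded that on the opposite strand by a median of 4.95 (log2) at 3 h, 4.71 at 4 h and 4.37 at 7 h. The same difference was 2.49 at 5 h, 2.75 at 48 h, 1.27 at 24 h and 0.81 at 1 h. Across genes, which are not independent replicates, the signal opposite to a gene followed that of the gene itself with a Spearman rho of 0.951 on the 1 h array and 0.521 on the 3 h array.

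**Figure D1:**
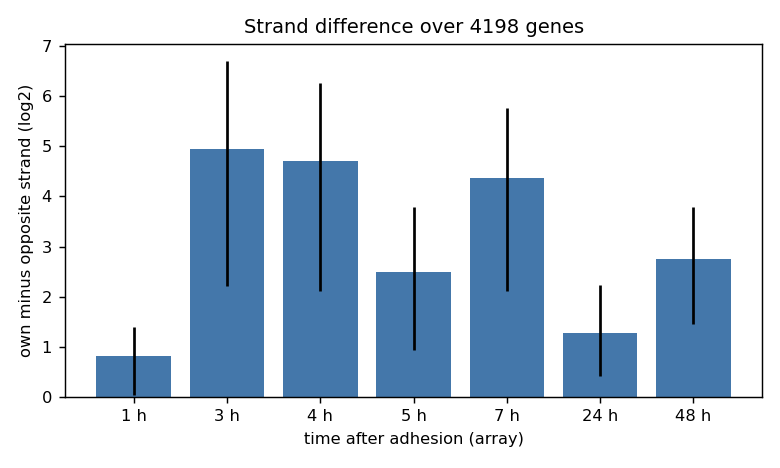
Median difference between a gene's own strand and the opposite strand (log2, vertical axis) on each of the 7 arrays (horizontal axis, hours after adhesion), over 4198 genes. Bars start at 0 and vertical lines span the quartiles over genes. The 1 h array (0.81) and the 24 h array (1.27) separate the strands least.

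The first comparison asks what differed between the earliest attached cells and the biofilm at 7 h. Genes for lipopeptides and for the amyloid fibre were higher at 7 h. The plipastatin synthetase genes, which make a lipopeptide, were at least 17.0-fold higher at the median of 5 genes, and the surfactin synthetase genes were 19.7-fold higher at the median of 4. The amyloid fibre and hydrophobin genes were at least 7.29-fold higher at the median, with *tasA*, the fibre subunit, at 4.37 ± 0.15 (SE over 33 probes) and *bslA*, the surface hydrophobin, at least 17.6-fold higher. Purine biosynthesis genes were 24.7-fold higher, whereas genes of the defective prophage PBSX were 10.6-fold lower, tryptophan biosynthesis genes 8.80-fold lower and histidine biosynthesis genes 5.48-fold lower. Both arrays lay on 1 slide and were scanned on the same day, and the 1 h array hardly separated the strands.

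Of 45 gene lists, 16 were higher and 5 lower at 7 h, by at least 2-fold at the median and outside the range of 95% of random lists. With dim genes at their lower bounds, the medians of 2 of the 16 were under 2-fold. The bacilysin list (0.95) and the *ydaJKLMN* exopolysaccharide list (0.28) were not called. All 15 genes of the *eps* operon, which makes the matrix exopolysaccharide, were at least 2-fold higher (median at least 3.20-fold), with *epsA* at 1.73 ± 0.08 and *epsN* at least 4.62-fold higher. All 5 poly-gamma-glutamate genes were at least 2-fold higher (median at least 4.57-fold), among them *edmS*, at least 20.6-fold, and *capC*, at least 6.85-fold, with no probe well above background at 1 h. In the subtilosin locus, which makes a bacteriocin, 9 of 9 genes were at least 4-fold higher (median at least 10.8-fold), among them *sboX*, at least 24.3-fold, and *albA* (3.72 ± 0.07). The bacillaene synthesis list (median 2.35) had 12 of 16 genes at least 4-fold higher, for example *pksJ*, at least 10.1-fold higher. The cannibalism toxin list was at least 2.04-fold higher, and 10 of its 11 genes had fewer than 50% of their probes well above background at 1 h. Arginine catabolism was at least 6.27-fold higher, with *rocB* at least 9.84-fold.

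Anaerobic and overflow metabolism genes were higher at 7 h as well. Nitrate and nitrite respiration had 7 of 13 genes at least 4-fold higher (median 2.03), including the nitrate reductase genes *narG* (4.73 ± 0.04) and *narH* (5.04 ± 0.05). The fermentation and microaerobic oxidase list (median 1.30) was led by *alsS* (4.00 ± 0.05) and *alsD* (3.93 ± 0.06), which make acetoin. Pyrimidine biosynthesis genes were 13.4-fold higher, with *pyrB* at 4.75 ± 0.05. The general stress list under SigB was at least 1.57-fold higher, with 11 of 28 genes dim at 1 h and *gsiB* at 3.74 ± 0.12, although *sigB* itself differed by -0.69 ± 0.05. The extracellular protease list was at least 1.51-fold higher, with *bpr* at 2.32 ± 0.05. The late motility list under SigD was at least 2.22-fold higher, with *motA* at 2.35 ± 0.12, whereas *hag*, the flagellin gene, differed by -0.04 ± 0.06. Among the genes lower at 7 h, 30 of 32 PBSX genes were at least 4-fold lower, among them *xlyA* (-3.93 ± 0.05) and *xkdM* (-3.76 ± 0.05). All 6 tryptophan genes were at least 4-fold lower, with *trpB* at -3.15 ± 0.05, and 7 of 8 histidine genes, with *hisF* at -2.90 ± 0.04. Heat shock genes were 2.74-fold lower, with *clpP* at -2.37 ± 0.08 and *groEL* at -1.64 ± 0.04. Branched-chain amino acid biosynthesis genes were 2.59-fold lower, with *leuD* at -2.69 ± 0.12.

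The 12 largest positive differences, ranked as measured, included *yjdB*, at least 16.9-fold higher, *liaI*, at least 45.9-fold, and *liaH* (5.26 ± 0.12) of the cell envelope stress operon *lia*, *pelA*, a pectate lyase gene, at least 11.7-fold, *csn*, a chitosanase gene, at least 32.5-fold, and *nadC*, an NAD synthesis gene, at least 23.9-fold. Of the 12 genes with the largest negative differences, 7 had more signal on the opposite strand than on their own on the 7 h array, namely *yoyB*, *ytoA*, *ytzH*, *yocN*, *ykzO*, *antE* and *yppC*. With both strands added, their differences were -1.28 for *yoyB* (-5.29 on its own strand), -2.02 for *ytoA* (-5.19), -0.40 for *ytzH* (-5.05), -0.43 for *yocN* (-4.76), -0.37 for *ykzO* (-4.23), 0.01 for *antE* (-4.18) and 1.15 for *yppC* (-3.93). The own-strand values in brackets are as measured. Dim at 7 h were *ytzH*, *ykzO* and *yppC*, which as lower bounds were at least 33.2-fold, 9.73-fold and 12.7-fold lower on their own strand. The other 5 had more signal on their own strand at 7 h: *ndhF* (-4.31 ± 0.04), *ybcI* (-4.23 ± 0.13), *ykzK* (-4.21 ± 0.12), *ybcC* (-4.03 ± 0.03) and *ybcF* (-4.02 ± 0.08). With both strands added these kept -4.57, -4.47, -3.97, -4.33 and -4.70.

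Of 5047 features well above background on at least 1 of the 2 arrays, 1316 were at least 4-fold higher and 210 at least 4-fold lower at 7 h on the 75th percentile scale. Relative to the median gene the split was 386 higher and 519 lower, and on the spike-in scale, which moved the median gene by 4.71, it was 4744 and 5. That shift exceeds the difference of every list named as lower. Set against the 3 h array, the pyrimidine list (0.23), the surfactin list (0.87) and the protease list (0.23) were no longer 2-fold higher, the late motility list was lower (-0.75), and the PBSX and tryptophan differences shrank to -1.63 and -1.56. With both strands added, the poly-gamma-glutamate median was 2.15 in place of a measured 3.68, and the medians of the late motility list (0.88) and the SigB list (0.96) lay under 2-fold. With the signal of probes without a gene subtracted, the protease and cannibalism lists both stood at -0.15 and the SigB list at -0.00.

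The second comparison asks what differed between the biofilm at 7 h and at 24 h. Genes for the use of acetoin and inositol were much higher at 24 h, and genes for nucleotide and histidine synthesis, fermentation and the *eps* operon were lower. The 5 acetoin catabolism genes were 357-fold higher at the median, led by *acoB*, at least 533-fold, and *acoA*, at least 495-fold. The 10 inositol catabolism genes were 198-fold higher at the median, with *iolF* at 8.32 ± 0.10. Pyrimidine biosynthesis genes were 16.7-fold lower, purine biosynthesis genes 12.1-fold lower and histidine biosynthesis genes 19.1-fold lower. The arrays differed in slide and scan day. Against the 5 h array, which shares the scan day of the 24 h array but not its slide, acetoin genes were 266-fold and inositol genes 177-fold higher at 24 h, and histidine genes 61.8-fold and pyrimidine genes 21.6-fold lower, whereas 3 lists called lower against 7 h were not called against 5 h, namely amyloid (0.06), ribosomal proteins (-0.88) and glycolysis (-1.29). Called only against 5 h were poly-gamma-glutamate (5.87-fold higher), subtilosin (2.72-fold higher) and SigF and SigE genes (at least 3.52-fold higher). The flagellar operon (3.29-fold lower), nitrate respiration (2.48-fold lower) and tryptophan synthesis (3.98-fold lower) were too. Of 5 poly-gamma-glutamate genes 3 were at least 2-fold higher. The median gene, *capB* (2.552, or 1.815 with both strands added), had more signal on the opposite strand on both arrays. The 24 h array separated the strands less than the 7 h array.

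Of the 45 lists, 7 were higher and 10 lower at 24 h. In gluconeogenesis 2 of 3 genes were higher, *gapB* (6.73 ± 0.10) and *pckA* (5.49 ± 0.08), and *fbp* differed by -0.61, while *ptsG*, the glucose transporter gene in the glycolysis list, had a difference of -5.08 ± 0.02. In the glycolysis list 11 of 13 genes were at least 2-fold lower (median -1.37), including *cggR* (-2.62 ± 0.04) and *pfkA* (-2.21 ± 0.05). All 10 fermentation and microaerobic oxidase genes were at least 4-fold lower (median -3.26), among them *lctE*, lactate dehydrogenase (-3.66 ± 0.06), *alsS* (-3.60 ± 0.03) and *cydD* (-3.53 ± 0.05). All 10 pyrimidine genes and 13 of 14 purine genes were at least 4-fold lower, for example *pyrB* (-5.41 ± 0.05), *pyrC* (-4.94 ± 0.05), *purQ* (-4.22 ± 0.03) and *purC* (-4.11 ± 0.05). The purine salvage genes *guaC* (-5.29 ± 0.07), *pbuX* (-4.82 ± 0.08) and *xpt* (-4.58 ± 0.13, with more signal on the opposite strand at 24 h) were lower too. The histidine genes were led by *hisB* (-5.11 ± 0.06) and *hisD* (-4.44 ± 0.07). Ribosomal protein genes were 2.08-fold lower at the median of 55, with *rpsD* at -2.40 ± 0.06.

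All 15 *eps* genes were at least 2-fold lower at 24 h (median -2.43), with *epsH* at -2.90 ± 0.08. *epsA* was lower by -2.53 ± 0.10, or -1.88 with both strands added (more signal on the opposite strand at 24 h). *tasA* was lower by -3.83 ± 0.05 and *tapA* by -1.43 ± 0.15, and the hydrophobin gene *bslA* differed by -0.43 ± 0.05. Late motility genes were 2.39-fold lower, with *lytC* at -2.29 ± 0.03 and *fliD* at -2.13 ± 0.03. PBSX genes were 5.10-fold lower, with *xhlB* at -3.15 ± 0.13. Higher at 24 h were the SigB list (3.45-fold), with *nhaX* (3.96 ± 0.04), *katE*, a catalase gene (3.44 ± 0.04), and *sigB* itself (2.41 ± 0.05). The protease list was 3.92-fold higher, led by *aprE* (3.97 ± 0.05). Bacilysin genes were 3.30-fold higher, with *bacF* at 2.42 ± 0.03. The sporulation initiation list was 2.41-fold higher, with *sigE* at least 5.30-fold and *sigF* at 1.62 ± 0.04, and with *spoIIGA* at least 4.81-fold, a gene with more signal on the opposite strand at 24 h. *sigE* and *spoIIGA* stayed below the median gene at 24 h (-1.52 and -1.72). The median signal of probes without a gene went from 155 at 7 h to 497 at 24 h, and that of gene probes from 2792 to 1150. Higher expression of *sigE* and *spoIIGA* therefore cannot be told apart from a rise of such signal. The later sporulation lists had positive medians, of 2.46 for SigF and SigE genes, 1.42 for SigG genes and 1.99 for SigK coat genes, all within the range of random lists of like expression. Against 5 h the SigF and SigE list was called, at least 3.52-fold higher. Genes of arabinose and maltose use were among the 12 largest positive differences as measured: *araQ* (at least 226-fold), *abnA* (139-fold), *araN* (166-fold), *araP* (231-fold), *abfA* (270-fold) and *malP* (374-fold), all lower bounds. So was *egsA*, a neighbour of *araN* on the chromosome (at least 212-fold).

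Of 5670 features, 986 were at least 4-fold higher and 743 at least 4-fold lower at 24 h on the 75th percentile scale, and 1210 and 416 relative to the median gene. More were lower than higher on the spike-in scale (588 higher, 1582 lower), under quantile normalization (369 and 1500) and after normexp (556 and 679). The same held with probes well above background on all arrays (302 and 739). More were higher with the percentile over probes detected on all arrays (1558 and 175) and the mean over probes (968 and 723). The median gene itself moved by -0.42, or by 0.57 when the percentile came from probes detected on all arrays and by -1.17 on the spike-in scale. Under quantile normalization the ribosomal protein list (0.50), the glycolysis list (0.28) and *srfAA* (0.49, against -1.21) had the opposite sign. For 48 h against 7 h bacilysin differed by -0.10.

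**Figure D2:**
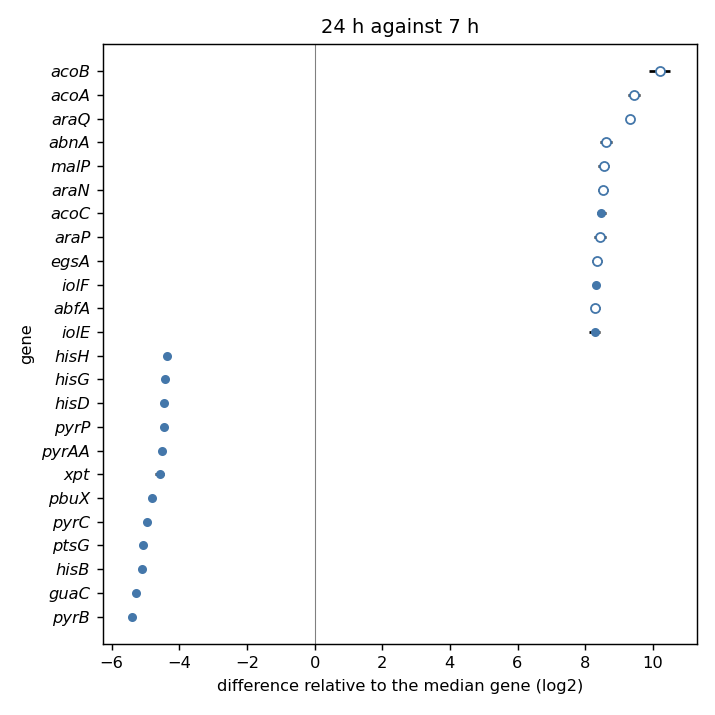
Difference between 24 h and 7 h (horizontal axis, log2, relative to the median gene) for the 12 genes with the largest positive and the 12 with the largest negative differences (vertical axis). Points are medians over the probes of a gene and bars the SE over its probes, which is measurement error within 1 pair of arrays. Open points mark genes with fewer than 50% of their probes well above background at 7 h, whose values rest on signal near background there. *pyrB* is lowest at -5.41.

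The third comparison asks what differed between 24 h and 48 h. Spore coat genes were higher at 48 h and inositol catabolism genes lower. Single genes for the use of maltodextrin and galactan, which no list fixed beforehand covers, had the largest negative differences. The SigK coat list was 7.30-fold higher at the median of 29 genes, and 26 of these were at least 2-fold higher. *cotG* was higher by 7.82 ± 0.10 (24 probes), or by 7.02 with both strands added (more signal on the opposite strand at 24 h), and *cotX* by 6.89 ± 0.13 (22 probes). *malA*, a maltose-6-phosphate glucosidase gene, had a difference of -5.83 ± 0.04 (60 probes). Both arrays lay on 1 slide and were scanned on the same day.

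Further coat and crust genes with large positive differences were *cotV* (6.66 ± 0.12), *cotW* (6.28 ± 0.17), *cgeA* (5.77 ± 0.19), *cotY* (5.65 ± 0.12) and *cgeB* (5.49 ± 0.14). The sporulation genes *spoVIF* (5.70 ± 0.21) and *spoVFB* (4.50 ± 0.08, or 3.50 with both strands added), a dipicolinate synthase subunit gene, were also higher. *spoVFB* had more signal on the opposite strand at 24 h. Arginine catabolism was the other list higher at 48 h (3.05-fold), with *rocB* (2.05 ± 0.03) and *rocA* (1.87 ± 0.03). The lists lower at 48 h numbered 5. Bacilysin genes were 3.97-fold lower, with *bacE* at -2.12 ± 0.03, and all 10 inositol genes were at least 2-fold lower (median -1.89). Arginine biosynthesis (median -1.58) was led by *argB* (-1.93 ± 0.11) and the *ydaJKLMN* exopolysaccharide genes (median -1.30) by *ydaM* (-1.68 ± 0.08). Histidine biosynthesis (median -1.28) was led by *hisZ* (-1.89 ± 0.08, with more signal on the opposite strand at 24 h). In this order, the median levels of these lists at 24 h were -1.24, -1.56 and -1.26. The median signal of probes without a gene went from 497 at 24 h to 188 at 48 h, and that of gene probes from 1150 to 1122. For these weak lists, lower expression therefore cannot be told apart from a loss of such signal. The genes *malR* (-5.58 ± 0.05), *malP* (-5.33 ± 0.04), *ganQ* (-5.07 ± 0.05), *ganA* (-4.98 ± 0.02), *mdxJ* (-4.63 ± 0.04) and *gutB* (-4.59 ± 0.06) had the next largest negative differences besides other members of the same operons. *tasA* was higher by 1.28 ± 0.04. *slrR*, a matrix regulator gene, had a difference of -1.57 ± 0.08, or -1.41 with both strands added (more signal on the opposite strand at 24 h). *hag* (0.25 ± 0.03), *spo0A* (0.47 ± 0.04) and *srfAA* (0.02 ± 0.02) lay nearer to 0.

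Of 5670 features, 167 were at least 4-fold higher and 48 at least 4-fold lower at 48 h, and 96 and 132 relative to the median gene, which itself moved by 0.50. The lists called lower numbered 5 in the main setting, 3 after normexp and 12 after quantile normalization of all probes.

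**Figure D3:**
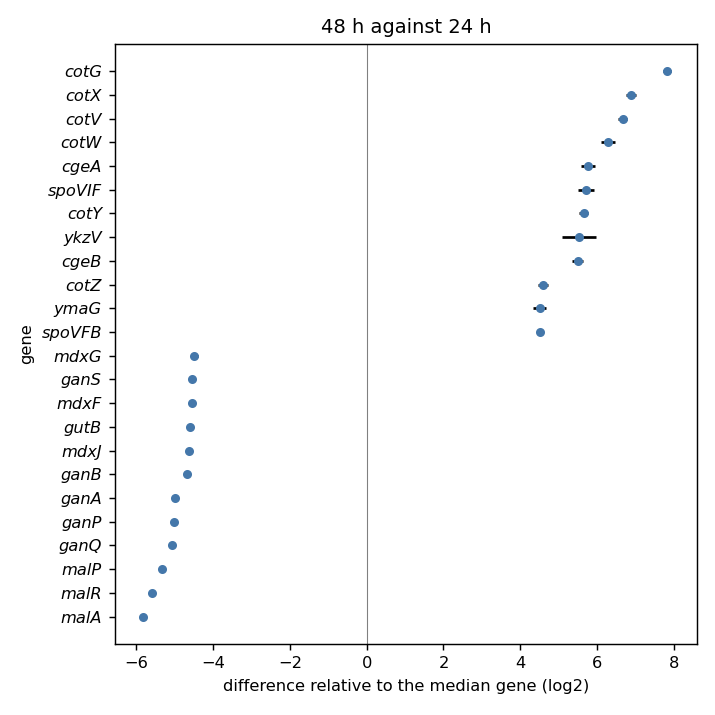
Difference between 48 h and 24 h (horizontal axis, log2, relative to the median gene) for the 12 genes with the largest positive and the 12 with the largest negative differences (vertical axis). Points are medians over the probes of a gene and bars the SE over its probes, which is measurement error within 1 pair of arrays. Spore coat genes lead, with *cotG* at 7.82, and *malA* is lowest at -5.83.

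Levels of the regulators and markers chosen beforehand followed different courses. *hag* (probes from 3634993 to 3635883 on the minus strand of the reference chromosome, genome build not given in the sources used here) lay between 5.60 and 6.97 above the median gene on all 7 arrays. *tasA* (probes from 2553095 to 2553857, minus strand) lay at -1.39 at 3 h, 3.27 at 7 h and -0.56 at 24 h. *tapA* lay at -3.84 at 3 h, -0.41 at 7 h and -1.84 at 24 h. *bslA* (probes from 3187512 to 3188035, plus strand) lay at -3.08 at 3 h, 2.81 at 7 h and 3.27 at 48 h. *epsA* lay at 1.18 at 7 h and -1.78 at 48 h. *sinI*, whose product is an antirepressor of matrix genes, lay at 1.22 at 7 h, and *sinR*, the repressor, between 0.55 and 1.85 on all arrays. *abrB*, a transition state regulator gene, lay at 5.47 at 1 h and 2.74 at 7 h. *srfAA* (probes from 376971 to 387703, plus strand) lay at 0.59 at 1 h, 4.16 at 3 h and 5.07 at 7 h. *sigD* lay between 2.46 and 4.24, *comK*, the competence regulator gene, between -3.59 and -1.46, and *sigG* between -3.81 and -0.95.

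**Figure D4:**
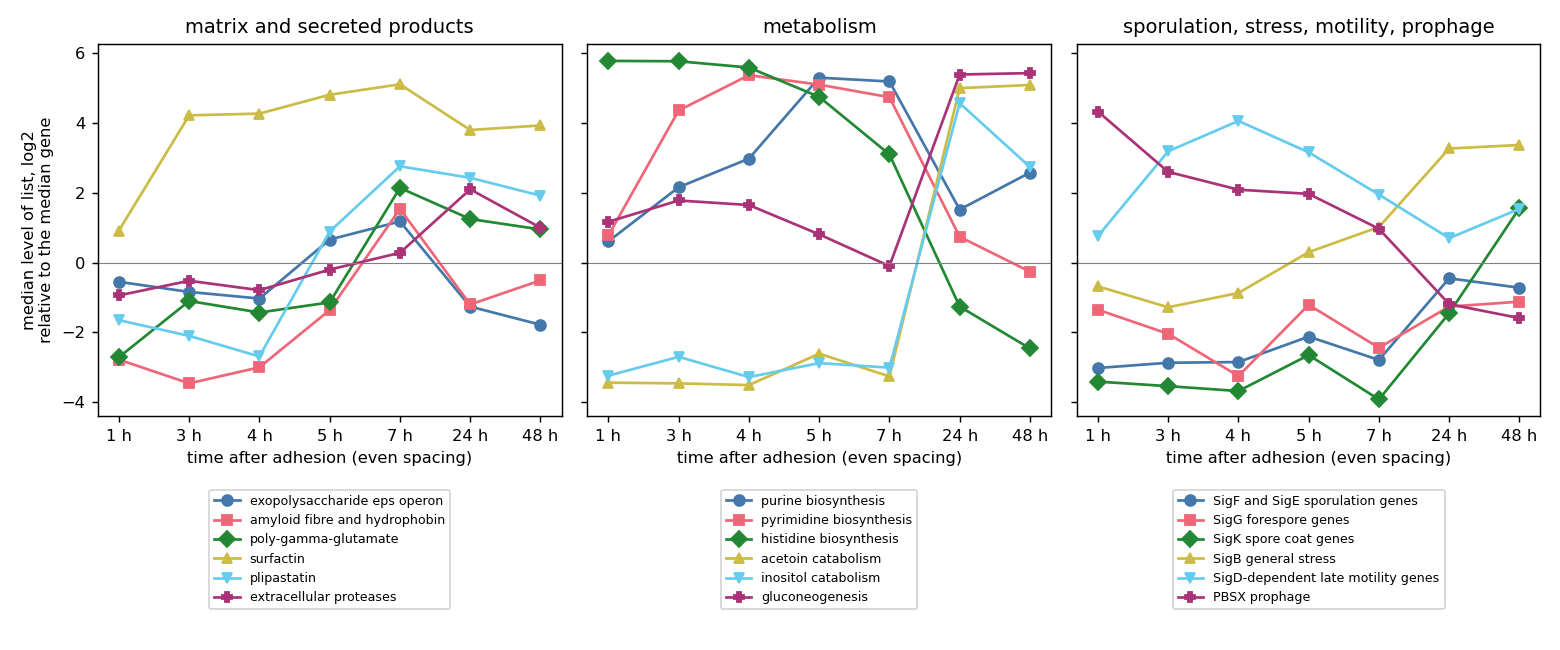
Median level of 18 gene lists (vertical axis, log2, relative to the median gene of each array) at the 7 time points (horizontal axis, hours after adhesion, evenly spaced and not to scale). Each point is the median over the genes of a list on 1 array. The *eps*, amyloid and poly-gamma-glutamate lists are highest at 7 h, acetoin and inositol catabolism are high from 24 h on, and the SigK coat list has its highest level at 48 h.

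The fourth analysis asks which genes rose or fell over the 7 time points, tested with limma against log2 of the hours with Benjamini-Hochberg adjustment. General stress genes, SigK coat genes and SigF and SigE sporulation genes rose, and PBSX genes fell. As lists these passed in camera with a preset correlation and in fry (adjusted p 0.0376 or less) but not in camera with an estimated correlation (0.148 for SigB and 0.622 for the other 3), and with slide as a term the SigK list pointed down. Of 28 SigB genes 23 rose, of 29 SigK coat genes 24 rose, and of 30 SigF and SigE genes 20 rose, whereas 30 of 32 PBSX genes fell. Adjusted over the list alone, the counts were 27, 27, 25 and 30. Over all features, 1054 rose and 133 fell of 5940, or 556 and 1084 when arrays were scaled by the median gene. The list counts, slopes and fry results of the trend rest on the main values, not on levels relative to the median gene. A shift common to all genes therefore enters them. The median slope over all features was 0.062 on the main values and -0.067 with arrays scaled by the median gene. By list it was 0.961 for SigB, 0.873 for SigK, 0.684 for SigF and SigE, and -0.998 for PBSX genes on the main values. How far fry depends on the scaling was not tested. The genes with the smallest p were *ykzI* (slope 1.58 ± 0.17 per doubling of time), *fadN* (1.74 ± 0.19) and *fadA* (1.67 ± 0.20), which act in fatty acid degradation, *ywmC* (1.58 ± 0.18), *bglS* (1.49 ± 0.18), *tdh* (1.38 ± 0.17), *mgsR* (1.18 ± 0.15), a regulator gene of the stress response, and *ntdB* (1.44 ± 0.18), each with an adjusted p of 0.00204 (limma, 7 arrays). Those that fell were the PBSX genes *xkdM* (slope -1.15 ± 0.17), *xkdK*, *xlyA*, *xkdI*, *xkdH*, *xkdE*, *ykzL* and *xepA*, with adjusted p from 0.00225 to 0.00239 (limma). With scan day as a term, limma called 0 genes in either direction, and 685 rose and 72 fell at an unadjusted p under 0.05. For the 1187 genes that rose or fell, the median size of the slope was 0.80 with a median SE of 0.19, and with scan day as a term 0.66 with an SE of 0.27. Of all 144 orders of the time points within scan days, 19, the real one included, gave at least as many genes, the highest 1998, and the 96 orders that moved the 5 h array gave 0. Without the 1 h array 1210 rose and 1439 fell, and without the 48 h array 369 and 291.

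In the gene list test, 13 lists rose and 13 fell with a preset correlation of 0.01, and 0 passed with an estimated correlation, where the adjusted p was 0.148 for SigB and 0.622 or more for the others. With slide as a term the test pointed the other way for 8 lists, among them the SigK coat (adjusted p 0.915, down) and inositol lists (0.537, down) and the flagellar operon (8.28e-07, up). Of the lists that rose, acetoin catabolism had 5 of 5 genes rising, inositol catabolism 10 of 10, subtilosin 9 of 9, plipastatin 5 of 5, cannibalism toxins 7 of 11, extracellular proteases 5 of 7, bacillaene synthesis 5 of 16, competence 8 of 20, the TCA cycle 4 of 12 and arginine catabolism 2 of 6. Adjusted over the list alone, these counts were 5, 10, 9, 5, 10, 5, 7, 9, 5 and 6. Of the lists that fell, histidine biosynthesis had 8 of 8 genes falling, tryptophan biosynthesis 6 of 6, glycolysis 2 of 13 and heat shock 1 of 12, and adjusted over the list alone 8, 6, 2 and 0. Ribosomal proteins had 2 genes rising and 2 falling of 55, with 0 and 1 when adjusted over the list alone. No gene passed in the other 6 lists that fell, which were aminoacyl-tRNA synthetases, branched-chain amino acid biosynthesis, fermentation, the flagellar basal body and chemotaxis operon, pyrimidine biosynthesis, and RNA polymerase and translation factors, and adjusted over the list alone the count stayed 0. The SPβ prophage list fell as well (1 gene rising, 0 adjusted over the list alone), with 3 of its 141 genes well above background on the 7 h or 24 h array, so its values lie at the floor.

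The other 19 lists did not pass the list test. Single genes rose in SigG forespore genes (8 of 22), sporulation initiation (5 of 11), poly-gamma-glutamate (3 of 5), gluconeogenesis (2 of 3), glycerol use (2 of 5) and the amyloid list (1 of 4), with the same counts adjusted over the list alone. Bacilysin had 0 of 7 genes rising, and 6 adjusted over the list alone. The adjusted p was 0.181 for *eps* (camera, preset correlation), 0.352 for surfactin, 0.898 for purine biosynthesis, 0.992 for arginine biosynthesis, 0.925 for ATP synthase, 0.0633 for cell division, 0.076 for nitrate respiration, 0.293 for phosphate starvation and 0.489 for the *ydaJKLMN* genes. For matrix regulators (0.263), iron uptake (0.898) and late motility (0.3) the median slope was positive while the test pointed down.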

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

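The tests of scan day, of the spike-in probes and of ribosomal RNA were chosen after the results were seen; the others below were fixed before their values were known.

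Probes without a gene name lie outside the comparisons and carried signal on all arrays. Their share well above background was 48.9% at 1 h, 33.4% at 3 h, 34.2% at 4 h, 77.4% at 5 h, 46.7% at 7 h, 95.9% at 24 h and 79.5% at 48 h. For genomic DNA as the whole source, the test was a correlation on the 24 h array between such probes lying near each other on one strand. After GC content and probe length were taken out it was 0.57, past the bound set beforehand against DNA. The 3, 4 and 7 h arrays, with less such signal, gave 0.432, 0.431 and 0.442. The test therefore cannot single out the added signal at 24 h, and genomic DNA stays open. Copies of the opposite strand would make the signal opposite to a gene move with the gene, and the differences between 24 h and 7 h correlated across genes with a Spearman rho of 0.365, between the bounds of 0.5 and 0.2 set beforehand, which leaves this open. Scan day stays open too, since every array of day 2 lay at least 28.5 percentage points above every array of day 1, and antisense transcription at these times was not tested.

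The 1 h array had a low gene signal that was nearly alike on both strands (median difference 0.81). Weaker labelling or hybridization is argued against by the spike-in probes, which differed from those at 3 h by -0.017 (log2). The ribosomal RNA probes, relative to the spike-ins, differed by 0.066 and so gave no sign of less bacterial RNA. They lay between 5.556 and 6.145 above the spike-ins on all 7 arrays. Whether such bright probes respond to the amount of RNA was not tested, so less bacterial RNA stays open. The signal opposite to genes at 1 h followed that of the genes themselves at 3 h with a Spearman rho of 0.916, and ribosomal RNA separated the strands by 3.84 at 1 h against 7.00 to 8.36 on the other arrays. Of 223 genes at least 4-fold lower at 7 h than at 1 h relative to the median gene, 14.3% had more signal on the opposite strand at 7 h, against 8.93% of the other 3975 genes, between the bounds of 30% and 10% set beforehand, so that the opposite strand may be behind some of these differences and not shown to be behind most; with both strands added, 173 of the 223 stayed at least 4-fold lower. A different labelling or amplification of the 1 h sample stays open, and a smaller share of mRNA in newly attached cells was not tested.

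For the genes that rose or fell over time, 1 of 100 orders of the 7 time points, the real one, gave as many (1187), and the highest other gave 633. This argues against a chance order of all 7 arrays. It cannot tell a course over the hours from a single step, since a step between 7 h and 24 h called 1027 rising and 568 falling. With scan day as a term limma called 0 genes, since the median SE went from 0.19 to 0.27 while the median size of the slope went from 0.80 to 0.66. Of the 144 orders of the time points within scan days 19, the real one included, gave as many genes, between the bounds of 50% and 5%, so scan day and biofilm age cannot be told apart for these genes as a set. In the 1187 genes, the 24 h array differed from the 5 h array of the same day by a median of 1.99 (quartiles 1.17 and 3.00) along the trend. These genes were selected with both arrays, so this difference cannot weigh on scan day. Against scan day alone goes the position of the 5 h array in 1029 genes selected without it. There it lay at 0.29 (quartiles 0.13 and 0.49) of the way from day 1 to day 2. Yet this is 1 array, and over all features the slopes within day 1 and within day 2 had a Spearman rho of -0.069. Slide stays open too, since slide 4 holds the 24 h and 48 h arrays alone.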

How the results depend on the processing

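No paired analysis was possible because each time point has 1 array and the comparisons have no test. Among the counts, 144 stayed within 1.5 times of the main value and 92 did not. Among the lists and named genes of the comparisons, 1802 values stayed, 1105 moved by more than the SE of the gene or a fixed part of the range of random lists, and 24, from called lists or genes at least 2-fold apart, changed sign, and among list trends 945 stayed, 105 were weaker, 65 stronger and 10 pointed the other way. Signal over background limits the 1 h array most, where 64.6% of gene probes were well above background. The alternatives differ in construction, and unless a threshold or the number of genes explains a change, the cause was not tested.

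The main counts of genes higher and lower were 1316 and 210 for 7 h against 1 h, 986 and 743 for 24 h against 7 h, and 167 and 48 for 48 h against 24 h, and 1054 genes rose and 133 fell over time. A 2-fold threshold gave 2764 and 393, 1567 and 1931, and 926 and 388 in the same order, and an 8-fold threshold 527 and 101, 479 and 175, and 62 and 21.

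After normexp, 626 genes were higher at 7 h than at 1 h and 556 at 24 h than at 7 h, 3 lists were lower at 48 h in place of 5, and 293 genes rose and 64 fell. At 7 h against 1 h *comK* turned to -0.83 and *aprE* to -0.31. Quantile normalization gave 369 higher and 1500 lower at 24 h than at 7 h, 621 higher at 48 h than at 24 h, 12 lists lower at 48 h, 514 genes rising and 7 lists falling in place of 13. At 24 h against 7 h it turned ribosomal proteins to 0.50, glycolysis to 0.28 and *srfAA* to 0.49, and the flagellar operon trend pointed up (adjusted p 0.932).

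Scaling by the median gene gave 386 higher and 519 lower at 7 h than at 1 h, 416 lower at 24 h than at 7 h, 96 higher and 132 lower at 48 h than at 24 h, and 556 rising and 1084 falling. Spike-in scaling gave 4744 higher and 5 lower, 588 higher and 1582 lower, 81 lower in the 3 comparisons in order, and 8 falling. The percentile over probes detected on all arrays gave 723 higher, then 1558 higher and 175 lower, then 102 higher and 117 lower, and 289 falling, and it turned the shift of the median gene between 7 h and 24 h to 0.57. Using only probes well above background on all arrays gave 302 higher at 24 h than at 7 h, about 1.1e2 higher and 29 lower at 48 h than at 24 h, and 388 rising and 84 falling, with *comK* at -1.61 and *skfF* at -0.031 for 7 h against 1 h.

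The following settings were added after the data were seen. Quantile normalization of gene values gave 422 higher and 330 lower at 7 h than at 1 h, 207 lower at 48 h than at 24 h, 3 lists lower at 7 h than at 1 h, 3 lower at 48 h than at 24 h, and 665 rising and 728 falling. Subtracting the signal of probes without a gene gave 190 higher and 344 lower, then 293 higher and 272 lower, then 100 higher in the 3 comparisons, 6 lists lower at 24 h than at 7 h, and 61 rising and 223 falling. It turned proteases, cannibalism toxins, *tapA*, *slrR*, *comK*, *aprE*, *ysnF*, *ydaD*, *skfG* and *skfF* to -0.153 and SigB to -0.002 for 7 h against 1 h, where values reach the common floor, *tapA* to 0.153 for 24 h against 7 h, and the SPβ trend up (adjusted p 0.33). Adding both strands gave 673 higher and 103 lower at 7 h than at 1 h, 296 lower at 24 h than at 7 h, 89 higher at 48 h than at 24 h and 305 falling, with *antE* at 0.014 and *yppC* at 1.15. With 3 h in place of 1 h, 301 were higher and late motility was -0.75. With 48 h in place of 24 h, 313 were lower and bacilysin was -0.10.

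With 5 h in place of 7 h, 605 genes were higher at 24 h and the amyloid list stood at 0.062. The deposited values gave 483 higher and 418 lower at 7 h than at 1 h, 279 higher and 278 lower at 48 h than at 24 h, and 651 rising and 768 falling. Leaving out 1 array at a time gave 369 to 1210 rising and 51 to 1439 falling. With slide as a term 1685 rose, 203 fell and 4 lists fell, and the test pointed up for aminoacyl-tRNA synthetases (adjusted p 0.766), fermentation (0.0398), the flagellar operon (8.28e-07), pyrimidine synthesis (0.000357), ribosomal proteins (0.832) and RNA polymerase (0.609), and down for inositol (0.537) and SigK coat genes (0.915). With scan day as a term 0 rose and 0 fell. A step between 7 h and 24 h gave 568 falling. With an estimated correlation 0 lists rose and 0 fell, and with fry 3 fell.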

Other observations

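The list of carbohydrate genes below was chosen after the results were seen, from genes seen to differ; the test of the silent regions was fixed before its value was known.

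Some genes for the use of carbohydrates other than glucose had their highest level at 24 h. For 28 genes of arabinose, maltodextrin, galactan and glucitol use, the median level was -3.59 at 7 h, 3.71 at 24 h and -0.36 at 48 h. All 28 were at least 4-fold higher at 24 h than at 7 h (median 7.33), and 27 were at least 4-fold lower at 48 h than at 24 h (median -4.24). Random lists are no measure for these 2 differences, because the genes were chosen by them. Between 48 h and 7 h the median was 2.84. At 7 h, 13 of the 28 had fewer than 50% of their probes well above background, and with these at their lower bounds the median for 24 h against 7 h was 7.21. The parts differed between 48 h and 7 h, by 5.12 for arabinose genes and by 0.93 for galactan genes, the latter within the range of random lists. Of the lists fixed beforehand, inositol genes were also highest at 24 h (-3.01, 4.57 and 2.74 at 7, 24 and 48 h), and glycerol genes were not (2.15, 1.60 and 1.19). The list was built from genes seen to differ, so this describes 3 arrays and tests no cause.

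The SPβ prophage stood apart from the rest of the chromosome. Of 3031 probes of its 141 genes, 8.22% were well above background at 24 h, when 98.4% of the probes without a gene outside the region were. A total of 3 runs of at least 5 neighbouring genes, with 24 genes in all, had under 10% of their probes well above background on every array; they begin at *yorG*, *yonR* and *cwlP*, and the longest spans 15987 bases. Of the 141 genes, 19 lay in these runs. Inside the runs 5.77% of the probes without a gene were well above background at 24 h. This share lay below the 20% set beforehand for the hypothesis that NDmed lacks these regions of the reference chromosome or carries diverged copies. The runs were chosen by gene probes that were low on the 24 h array too. On that array the signal opposite to genes followed that of the genes (Spearman rho 0.784), so the choice favoured a low share. Expression arrays also cannot tell a missing region from a lack of transcription on both strands, so the hypothesis stays open. The low share does show that the high signal of other probes at 24 h was not spread over all probes of the array.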
